A study of Homo sapiens with 15 samples.

How the data were processed

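Poly(A)-enriched RNA of LHCN-M2 cells was made into strand-marking libraries with the NEBNext Ultra II Directional kit and sequenced as paired-end reads of 150 bp on a NovaSeq X, per the labels' protocols. The conditions were undifferentiated, differentiated, differentiated with 2 mM AICAR, and differentiated with 0.5 mM palmitate. Each of the 15 libraries was placed in its group by its title, and the AICAR group has no replicate 2 because the submitters left it out for low library concentration, per the labels' protocols.

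Tables of the whole series were used in both of their forms. The authors deposited raw counts per gene, and they deposited variance-stabilised values on a log2-like scale for the same genes and libraries. Reads were processed with STAR 2.7.9a, SAMtools, FastQC, MultiQC and DESeq2 1.34.0 on hg38, per the submitters' processing notes. The tool that counted reads per gene, its strand setting and the annotation release are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies (actins, ribosomal proteins and their pseudogenes, zinc finger genes, AKR1C genes) may have been divided between genes. The table held 16017 genes, and each had at least 10 counts in at least 3 libraries, so genes below that level were not analysed here; the deposited log2-like values had 1 common value, 2.85, wherever the count was 0. Gene identifiers carried a version; 15996 had a symbol in the name table and 15787 matched GENCODE release 29 on GRCh38 with coordinates, of which the coordinates printed here are taken, and 13060 genes were protein coding.

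Counts were tested with edgeR 4.0.16 (quasi-likelihood test, robust, two-sided) in 1 fit of all 15 libraries with a mean per group and TMM composition factors, after its filter on low counts, which kept 15741 genes and left out 276. The common biological coefficient of variation was 0.0824 and the residual degrees of freedom 11. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a comparison, with a threshold of 0.05; counts of larger changes also require 2-fold. Levels are CPM scaled by the TMM factors, with SD over the libraries of a group. Log2 fold changes of genes with few counts depend on edgeR's prior count, and genes with 1 to 3 counts over a group are given as a ratio with its 95% counting interval. Total counts, detection and shares of counts per library were compared by two-sided exact permutation tests.

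Gene lists (42) were tested with camera (limma 3.58.1) on the same counts, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 40 lists that had at least 5 tested members; the test was repeated with the correlation estimated from the data, and with fry. A member of a list is said to have risen or fallen when its adjusted p over all genes passed, and counts adjusted over the list alone are given where they differ. Camera compares a list with the other genes, and the estimated correlation allows for members that vary together.

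The comparisons, tests, gene lists, main alternatives and the rule for named genes were fixed before the data were examined. In each comparison the text names the 5 genes with the largest rise and the 5 with the largest fall among genes that passed, had a mean of at least 5 CPM over all libraries, did not overlap between the groups and had a symbol; a set of genes chosen for each comparison in advance; and in each main list up to 2 members, those with the smallest p among those that passed. Some genes that meet this rule are not reported here. Genes or sets chosen after values were seen are said to be so where they appear.

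The overlap of both treatment responses was set against 20 draws of unchanged groups simulated with the same controls, against independent lists, and against the 6 ways of dividing the 4 differentiated libraries 2 and 2. Every comparison was run on all 35 splits of its libraries into groups of the same sizes.

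The numbers of genes called and the named genes were recomputed with DESeq2 size factors in edgeR, with library totals only, with DESeq2 1.42.0, with limma on the deposited log2-like values, with no filter, with a minimum of 1 CPM in 3 libraries, with only the groups compared, with the replicate number as a block, with a threshold of 0.01, and without each library in turn. The lists were recomputed with the same settings except DESeq2 itself, and the overlaps with divided controls and with calls of at least 2-fold. After the data were seen, all libraries thinned to 9549050 counts and a fit with the trend on transcript length and GC content removed per library were added.

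The scripts were tested on simulated counts in which 200 genes were changed. For differentiated against undifferentiated cells, run on 15462 genes, 71.2%, 98.5% and 100% of the planted log2 changes of 0.5, 1 and 2 were recovered. In the simulation of AICAR against differentiated (15587 genes) the shares were 59.1%, 92.5% and 97.0%, in that of palmitate against differentiated (15477 genes) 78.8%, 98.5% and 100%, and in that of AICAR against palmitate (15619 genes) 75.8%, 88.1% and 98.5%. Between 8 and 17 unchanged genes were called per simulation. The planted list was called in each simulation. So was 1 of the 40 other lists, which held at least 1 planted gene. No libraries were duplicates: within groups the chi-square per degree of freedom between libraries ranged from 2.20 to 42.4. The work used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.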

Results

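Messenger RNA was sequenced from LHCN-M2 cells, an immortalised human skeletal muscle line that proliferates as myoblasts, carries transgenes for TERT and CDK4, and forms multinucleated myotubes when it is differentiated. The 15 libraries fell into 4 groups: undifferentiated cells (n = 4), differentiated cells (n = 4), differentiated cells given 2 mM AICAR (n = 3, replicates 1, 3 and 4) and differentiated cells given 0.5 mM palmitate (n = 4). AICAR is a nucleoside that cells phosphorylate to a mimic of AMP, which activates AMP-activated protein kinase (AMPK), and palmitate is the saturated fatty acid commonly used to load cultured muscle with lipid. The lengths of the exposures and the media are not given in the sources used here. The labels do not say that replicates came from separate cultures, so the p-values below measure the spread between these samples, which may be technical.

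Total counts were 24.64, 25.92, 35.12 and 23.1 M counts (M, mega) in undifferentiated replicates 1 to 4, and 32.62, 30.04, 29.56 and 30.84 M in differentiated replicates 1 to 4. They were 9.55, 12.13 and 10.95 M in AICAR replicates 1, 3 and 4, and 26.91, 20.53, 22.47 and 20.84 M in palmitate replicates 1 to 4. Totals were therefore lower with AICAR (10.9 ± 1.29 M, mean ± SD, n = 3) and with palmitate (22.7 ± 2.94 M, n = 4) than in differentiated cells (30.8 ± 1.345 M, n = 4). Each had a two-sided exact permutation p = 0.0286, the smallest that these group sizes allow. Undifferentiated cells (27.2 ± 5.41 M, n = 4) and differentiated cells had totals that differed by less than their spread (exact permutation p = 0.257). A count of 3 per library, taken here as the detection floor, corresponded to 0.279 counts per M (CPM) in the AICAR libraries and 0.0977 CPM in the differentiated libraries on average. Intervals and floors given here cover counting error only.

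The most abundant mRNAs took different shares of the libraries. The 10 most abundant genes held 8.34 ± 0.0485% of the counts in undifferentiated cells, 13.5 ± 0.395% in differentiated cells, 17.5 ± 1.26% with AICAR and 13.1 ± 0.549% with palmitate. Fibronectin mRNA (FN1) alone made up 4.25% of the counts in differentiated cells and 5.78% with AICAR, and COL1A1, the type I collagen alpha 1 chain, made up 3.73% and 4.46%. The composition factors (TMM, see the processing) lay between 0.706 and 0.805 in the AICAR libraries and between 1.03 and 1.09 in all others, so results that involve AICAR depend more on the scaling than the others do. On the first principal component of log2 CPM with TMM factors, with 52.8% of the variance, undifferentiated cells separated from the rest. The second, with 29.6%, separated the AICAR libraries.

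**Figure D1:**
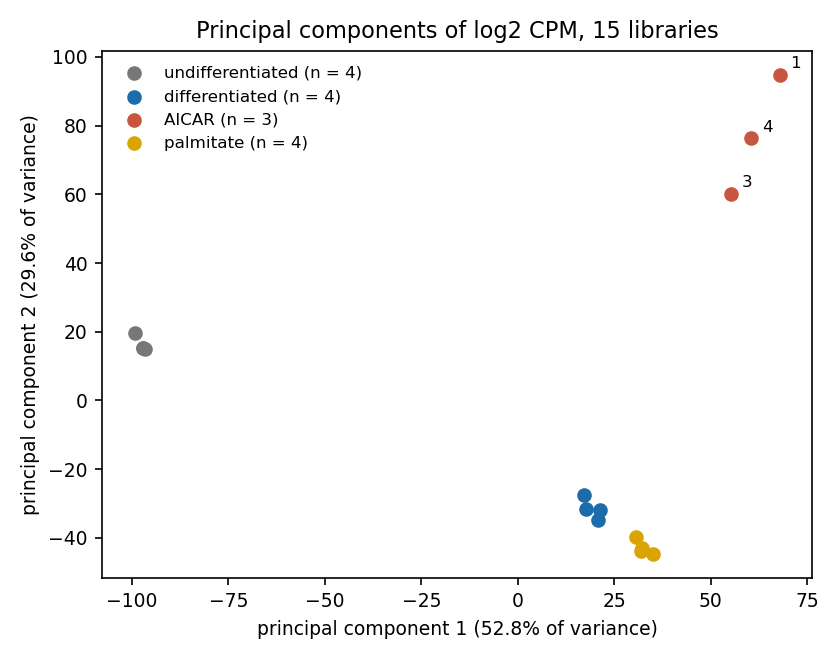
Principal components 1 and 2 of log2 CPM with TMM factors, with the percent of variance on each axis and 1 point per library, coloured by group. Component 1 holds 52.8% and component 2 holds 29.6% of the variance, and AICAR replicate 1 lies at 94.8 on component 2.

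The first comparison asked which mRNAs change when the myoblasts differentiate. Differentiated cells carried far more mRNA for the contractile apparatus. MYH3, the embryonic myosin heavy chain of newly formed myotubes, rose from 85.5 ± 4.87 to 3196 ± 613 CPM (mean ± SD, n = 4 in each group). CKM, the muscle creatine kinase that regenerates ATP from phosphocreatine, rose from 4.04 ± 0.402 to 331 ± 69.0 CPM, and ACTA1, the skeletal muscle alpha-actin, rose from 26.0 ± 4.47 to 483 ± 75.1 CPM. In the opposite direction, MYF5, a transcription factor of proliferating myoblasts, fell from 346 ± 4.75 to 10.7 ± 1.25 CPM, and MKI67, a marker of cycling cells, fell from 179 ± 8.77 to 31.5 ± 10.9 CPM. The log2 fold changes (± SE) were 5.23 ± 0.14 for MYH3, 6.36 ± 0.20 for CKM, 4.22 ± 0.15 for ACTA1, -5.01 ± 0.08 for MYF5 and -2.51 ± 0.26 for MKI67. Their edgeR adjusted p-values, in this order, were 3.06e-16, 3.11e-13, 1.74e-13, 1.42e-22 and 3.19e-06.

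On the GRCh38 (hg38) assembly, with gene bodies from GENCODE release 29, MYH3 (ENSG00000109063.15) spans 10628526 to 10657309 on the minus strand of chromosome 17. CKM (ENSG00000104879.5) spans 45306414 to 45322977 on the minus strand of chromosome 19, and MYF5 (ENSG00000111049.4) spans 80716912 to 80719673 on the plus strand of chromosome 12.

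Of 15741 genes tested, 5194 were higher and 4995 were lower in differentiated cells (edgeR quasi-likelihood test, adjusted p below 0.05), and 2194 and 1195 of these changed by at least 2-fold. The largest rises chosen by the fixed rule were those of CAPN6, a calpain family member (log2 fold change 9.96), the forkhead transcription factor FOXS1 (8.83) and the WASP-interacting protein WIPF3 (8.49). Next came the muscle protein ATP1B4 (8.46) and SLN, sarcolipin, a regulator of the sarcoplasmic reticulum calcium pump (8.43). CAPN6 had 2 counts over all undifferentiated libraries, so its change is better given as a ratio of 1290 with a 95% counting interval of 356.8 to 10660. FOXS1, WIPF3 and SLN had 4, 9 and 10 counts there. Their ratios had 95% counting intervals of 204 to 1922, 202.2 to 840.8 and 198.7 to 763.2. The largest falls were those of ZBTB16, a zinc finger transcription factor (-7.20), the VEGF receptor KDR (-6.90), the growth factor AREG (-5.87), the secreted pentraxin NPTX2 (-5.51) and MYF5.

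Within the lists of muscle genes, 45 of 46 sarcomere genes rose and 1 fell, with a median log2 change of 3.27 (camera adjusted p = 1.87e-50; adjusted p = 0.0107 with an estimated correlation). TMOD1, which caps thin filaments, rose by 4.51 log2 units to 83.9 ± 5.36 CPM, and LDB3, a Z-disc protein, rose by 4.31 to 115 ± 12.2 CPM. Of 21 calcium handling genes 18 rose, 2 fell and 1 did not pass (18 and 3 adjusted over the list alone). Among them were CASQ2, the calcium buffer of the sarcoplasmic reticulum (3.49), and CACNB1, a subunit of the voltage-gated calcium channel (2.73). The list passed with a camera adjusted p = 1.99e-12 (adjusted p = 0.0423 with an estimated correlation). Of 15 genes for muscle energy supply 13 rose and 2 fell, led by COX6A2, a muscle isoform of cytochrome c oxidase (4.63), and FABP3, a fatty acid binding protein (3.28). This list had a camera adjusted p = 2.76e-07, a call that was lost with an estimated correlation (adjusted p = 0.0935). At the neuromuscular junction 9 of 14 genes rose and 4 fell, including the agrin receptor LRP4 (1.56) and agrin itself, AGRN (1.22). This list had a camera adjusted p = 0.0297, which became 0.0961 when the trend on transcript length and GC content was removed, and an adjusted p = 0.41 with an estimated correlation. Myoblast fusion genes went both ways (3 rose, 3 fell and 4 did not pass; camera adjusted p = 0.261), with rises of the cadherin CDH2 (1.70) and the membrane repair protein DYSF (0.91).

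Genes of the myogenic lineage were divided. MYMK, the fusion protein myomaker, rose from 21.7 ± 1.32 to 129 ± 32.2 CPM (log2 fold change 2.57) and MYOG, myogenin, which drives terminal differentiation, rose from 85.2 ± 7.81 to 159.8 ± 39.0 CPM (0.91). MYOD1 fell from 240.3 ± 22.2 to 79.4 ± 24.9 CPM (-1.60). The fast adult myosin MYH2 rose by 1.22 log2 units to 26.3 ± 5.14 CPM. Of 20 myogenic differentiation factors 13 rose, 5 fell and 2 did not pass (14 and 5 adjusted over the list alone), among them the methyltransferase SMYD1 (2.54). The camera adjusted p was 0.00716 (adjusted p = 0.308 with an estimated correlation). Among 20 regulators of satellite cells and myoblasts 10 fell, 5 rose and 5 did not pass, with falls of the inhibitors of differentiation ID1 (-3.09) and ID2 (-1.65). The list passed in both forms of the test (camera adjusted p = 2.3e-04; adjusted p = 0.0122 with an estimated correlation). PAX7 was not in the table analysed.

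**Figure D2:**
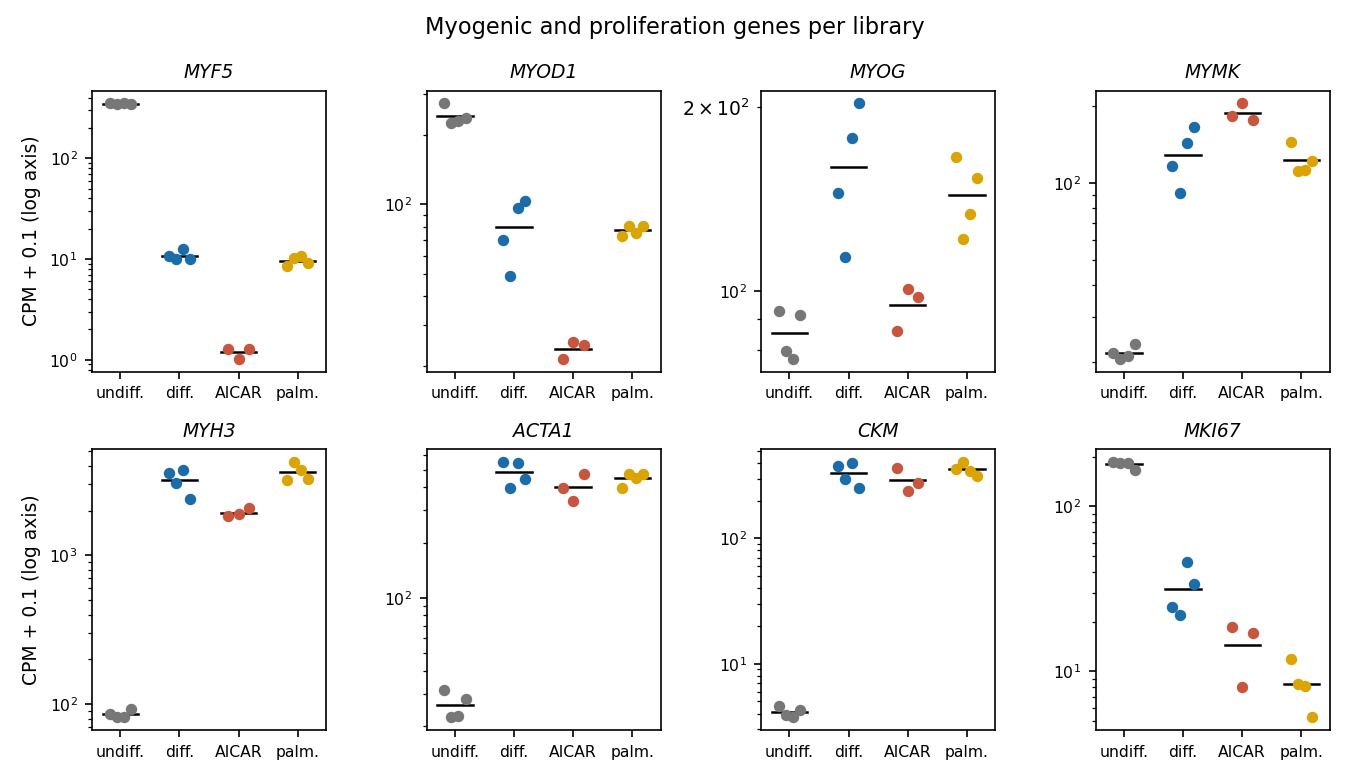
CPM plus 0.1 on a log axis for MYF5, MYOD1, MYOG, MYMK, MYH3, ACTA1, CKM and MKI67 in the 4 groups, with 1 point per library and a line at each group mean. MYF5 lies near 346 CPM in undifferentiated and 10.7 CPM in differentiated libraries, and MYH3 near 85.5 and 3196 CPM.

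Proliferation and growth genes were lower after differentiation. All 45 genes of DNA replication and mitosis fell, 44 of them by at least 2-fold, including the helicase subunit MCM4 (-1.83) and cyclin E2, CCNE2 (-2.97), with a camera adjusted p = 5.73e-25 (adjusted p = 0.0861 with an estimated correlation). Of 27 ribosome biogenesis genes 22 fell, 1 rose and 4 did not pass, led by MYC (-1.93) and the nucleolar methyltransferase FBL (-1.21). The camera adjusted p was 7.90e-06 (adjusted p = 0.0779 with an estimated correlation). Ribosomal protein genes, whose counts may be shared with processed pseudogenes, fell in 67 of 70 cases by a median of -0.44 (camera adjusted p = 1.32e-06; adjusted p = 0.578 with an estimated correlation). Genes for purine synthesis and salvage (17 of 23 fell and 3 rose; camera adjusted p = 5.88e-05; adjusted p = 0.027 with an estimated correlation) were lower as well. So were hypoxia-inducible genes (17 of 20 fell and 1 rose; 1.01e-07 and 0.0107 in the same order). Of 26 glycolysis genes 19 fell and 2 rose, with a median of -1.04 (camera adjusted p = 2.58e-11; adjusted p = 0.0614 with an estimated correlation). TERT and CDK4, whose counts join any endogenous mRNA with that of the transgenes, moved too: TERT fell from 1101 ± 45.1 to 531 ± 62.4 CPM and CDK4 from 116 ± 5.11 to 98.6 ± 11.97 CPM.

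Sterol synthesis had the largest share of genes that rose among the metabolic lists, 24 of 25, with a median of 1.55. It was called in both forms of the test (camera adjusted p = 1.30e-23, and adjusted p = 0.00352 with an estimated correlation). Nuclear genes for the respiratory chain and ATP synthase divided into 12 that rose, 9 that fell and 37 that did not pass (10 and 9 adjusted over the list alone; camera adjusted p = 0.997). COX6C was higher (0.68) and NDUFA12 lower (-0.58). Of the mRNAs encoded by mitochondrial DNA, 12 of 13 rose (camera adjusted p = 0.00268; adjusted p = 0.41 with an estimated correlation). Fatty acid oxidation genes also divided (9 rose, 4 fell and 7 did not pass; camera adjusted p = 0.874). Both of those with the smallest p fell: ACSL1, which activates long-chain fatty acids (-0.93), and ECI2, an enoyl-CoA isomerase (-0.48). Of 19 fatty acid synthesis genes 12 rose and 2 fell (camera adjusted p = 0.0127; adjusted p = 0.308 with an estimated correlation). Targets of the integrated stress response (27 of 33 rose and 2 fell; 1.25e-07 and 0.0807 in the same order) and of NRF2 (17 of 21 rose and 4 fell; 2.68e-04 and 0.084) passed with the preset correlation and not with the estimated one. So did genes of atrophy and autophagy (19 of 28 rose and 6 fell; 0.00429 and 0.0779).

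Extracellular matrix genes mostly rose: 25 of 37 were higher and 9 lower (26 and 9 adjusted over the list alone). COL4A2, a basement membrane collagen, rose by 1.85 log2 units to 788 ± 36.8 CPM, and TGFBI, a matrix protein, fell (-2.36). The camera adjusted p was 2.42e-04 (adjusted p = 0.533 with an estimated correlation). Of the marker lists of other cell types, 7 of 11 fibroblast markers rose and 3 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.00313; adjusted p = 0.142 with an estimated correlation). Of these 11, 9 lay at 10 CPM or more in differentiated cells, 3 belong to another list and 2 to the matrix list. Of 9 smooth muscle markers 6 rose and 2 fell (camera adjusted p = 1.24e-04; adjusted p = 0.0504 with an estimated correlation). Endothelial (2 of 7 rose and 4 fell; camera adjusted p = 0.291), leukocyte (1 of 5 rose and 1 fell; 0.997) and neural markers (1 of 5 rose and 2 fell; 0.595) did not pass. Adipocyte markers (2 of 4 rose and 1 fell) were too few to test. The fibroblast call did not hold with limma on the deposited variance-stabilised values (adjusted p = 0.0595).

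The second comparison asked how differentiated cells respond to AICAR. ARC, an activity-regulated gene best known from synapses, showed the largest rise under the fixed rule, from 0.482 ± 0.178 CPM in differentiated cells (n = 4) to 61.5 ± 18.2 CPM with AICAR (n = 3). NOCT, nocturnin, a phosphatase that acts on NADPH, rose from 23.1 ± 5.14 to 139.8 ± 29.9 CPM, and NFKB1, the p105/p50 subunit of NF-kB, rose from 53.5 ± 3.80 to 233 ± 26.6 CPM. TXNIP, an inhibitor of glucose uptake, fell from 105 ± 6.11 to 40.9 ± 2.45 CPM, and DDIT3 (CHOP), a stress-induced transcription factor, fell from 17.1 ± 1.36 to 3.19 ± 1.61 CPM. Log2 fold changes (± SE) were 6.98 ± 0.28 for ARC, 2.59 ± 0.16 for NOCT, 2.12 ± 0.08 for NFKB1, -1.36 ± 0.10 for TXNIP and -2.35 ± 0.20 for DDIT3. Their edgeR adjusted p-values, in this order, were 1.78e-12, 7.10e-10, 2.62e-15, 3.99e-11 and 7.09e-10. ARC (ENSG00000198576.4) spans 142611044 to 142614472 on the minus strand of chromosome 8, and NFKB1 (ENSG00000109320.13) spans 102501329 to 102617302 on the plus strand of chromosome 4.

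In this comparison 4753 genes were higher and 5669 lower with AICAR (edgeR, adjusted p below 0.05), and 1011 and 2749 of them by at least 2-fold. The split depended on the scaling: 45.6% of the calls were rises with TMM factors and 20.6% with library totals only, which moved the median change of all genes by -0.45 log2 units and turned 320 calls to the opposite direction. None of the genes named for this comparison changed sign with library totals only. AICAR replicate 1 lay apart from the other AICAR libraries on the fourth principal component (42.1, against -23.0 and -28.1), and 1 AICAR library had been excluded by the submitters for low concentration.

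The other large rises were those of the chemokine CXCL8 (log2 fold change 3.73), the proteoglycan ESM1 (2.99) and TAF3, a subunit of the general transcription factor TFIID (2.57). CXCL8 rested largely on 1 library: its 3 AICAR values were 6.23, 11.6 and 69.9 CPM, and without AICAR replicate 4 its change was 2.07 (edgeR adjusted p = 0.00286). The largest falls were those of the microRNA host gene MIR503HG (-5.56), cyclin E2, CCNE2 (-4.50), WDR5B (-4.45), FOXS1 (-4.14) and KCTD11 (-3.93). CCNE2 had 3 counts over the AICAR group, which gives a ratio of 23.5 with a 95% counting interval of 7.97 to 114. MIR503HG and WDR5B had 7 and 9 counts over that group, with intervals of 23.3 to 119.9 and 11.6 to 48.4 for their ratios. Leaving out 1 library moved MIR503HG to -6.71 (without AICAR replicate 4), CCNE2 to -5.30 (without AICAR replicate 3) and WDR5B to -5.27 (without AICAR replicate 3) or -3.83 (without AICAR replicate 4).

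The sarcomere and calcium handling lists did not pass with AICAR, with several marked falls among muscle genes. MYOG fell from 159.8 ± 39.0 to 94.7 ± 7.78 CPM (-0.75) and MYH3 from 3196 ± 613 to 1929 ± 126 CPM (-0.73). Of 46 sarcomere genes 10 rose, 16 fell and 20 did not pass (camera adjusted p = 0.604), with falls of XIRP1, an actin-binding protein of the sarcomere (-2.13), and LDB3 (-1.32). Among 21 calcium handling genes 6 rose, 10 fell and 5 did not pass (6 and 12 adjusted over the list alone; camera adjusted p = 0.316). RYR1, the calcium release channel (-1.46), and JPH2, which tethers it to the surface membrane (-1.93), both fell. Myogenic differentiation factors were lower as a list (10 of 20 fell and 3 rose, or 9 and 3 adjusted over the list alone; camera adjusted p = 0.0337). They did not pass with an estimated correlation (adjusted p = 0.495), with a minimum CPM of 1 (0.0516), with limma (0.123) or without differentiated replicate 3 (0.0531). Myoblast fusion genes rose in 7 of 10 cases (camera adjusted p = 0.0191; adjusted p = 0.414 with an estimated correlation and 0.0726 with library totals only). FBXO32, the muscle ubiquitin ligase atrogin-1, fell from 127 ± 5.16 to 71.5 ± 4.59 CPM (-0.82). In the list of atrophy and autophagy genes 13 rose, 9 fell and 6 did not pass (camera adjusted p = 0.213). The lysosomal genes CTSL (1.36) and LAMP1 (1.13) rose.

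Energy metabolism genes changed in separate directions. Of 58 nuclear genes for the respiratory chain and ATP synthase 53 rose, none fell and 5 did not pass, with a median of 0.74, among them NDUFA4 (1.18) and NDUFA1 (1.33). The camera adjusted p was 1.66e-15 (adjusted p = 0.242 with an estimated correlation). Of 13 mRNAs encoded by mitochondrial DNA 4 rose and 6 fell, with a median of -0.23 (camera adjusted p = 0.825), and with the length and GC trend removed this list was called lower (median -0.89, adjusted p = 9.1e-04). Their share of the counts was 1.90% with AICAR and 2.36% in differentiated cells (exact permutation p = 0.0286). Regulators of mitochondrial biogenesis did not pass as a list (2 rose, 9 fell and 8 did not pass; camera adjusted p = 0.142), and the coactivator PPRC1 (-1.60) and the mitochondrial DNA polymerase POLG (-0.73) fell. PPARGC1A, the coactivator PGC-1 alpha, measured 3.47 ± 2.30 CPM with AICAR and 3.67 ± 0.946 CPM without (adjusted p = 0.925), and the sign of its change depended on which library was left out (-0.59 without AICAR replicate 4 and 0.31 without AICAR replicate 1). The glucose transporter gene SLC2A4 (0.482 ± 0.403 against 0.287 ± 0.159 CPM, adjusted p = 0.289), hexokinase 2, HK2 (25.9 ± 8.19 against 30.4 ± 3.38 CPM, adjusted p = 0.13), and PDK4 (0.667 ± 0.46 against 0.39 ± 0.356 CPM, adjusted p = 0.315) did not pass in edgeR either. SLC2A4 changed sign without AICAR replicate 4 (-0.22). HK2 passed with library totals only (-0.67) and without AICAR replicate 4 (-0.48), and PDK4 passed without differentiated replicate 2 (1.72, adjusted p = 0.0227). CPT1B was not in the table analysed.

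Of 26 glycolysis genes 18 rose and 4 fell (camera adjusted p = 0.00847; adjusted p = 0.506 with an estimated correlation and 0.0726 with library totals only). Both named members, TXNIP and PFKFB3, which makes the activator of phosphofructokinase (-1.67), fell. Fatty acid oxidation genes had a median of 0.42 with TMM factors, with 14 of 20 higher and 1 lower, and a median of -0.03 with library totals only. The camera adjusted p was 0.0149 and 0.163 in the same order (adjusted p = 0.495 with an estimated correlation). In this list CPT2, the inner membrane carnitine palmitoyltransferase, fell (-1.54) and ETFA, an electron acceptor of the pathway, rose (0.89). Sterol synthesis genes divided (13 rose, 6 fell and 6 did not pass, or 14 and 6 adjusted over the list alone; camera adjusted p = 0.143). The methyl sterol oxidase MSMO1 rose (1.59) and squalene epoxidase, SQLE, fell (-1.25). Fatty acid synthesis genes included rises of the desaturases FADS1 (1.10) and SCD (1.03) among 11 that rose and 5 that fell of 19 (camera adjusted p = 0.0581). This list passed with DESeq2 size factors (0.0484), with limma (0.0484), with the length and GC trend removed (0.0021), and without AICAR replicate 1 (0.0487), AICAR replicate 4 (0.0337) or differentiated replicate 4 (0.0451). Its median was 0.39 with TMM factors and -0.07 with library totals only. Of 23 genes for purine synthesis and salvage, the route that handles AICAR, 12 rose and 3 fell (camera adjusted p = 0.128, and 0.0414 with limma), including the ectonucleotidase NT5E (1.23) and adenosine kinase, ADK (0.96).

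Stress and inflammatory lists held large changes of both signs. Of 33 integrated stress response targets 11 rose, 12 fell and 10 did not pass (camera adjusted p = 0.816), from the serine synthesis enzyme PSAT1 (1.13) to DDIT3. The stress cytokine GDF15 rose from 123 ± 9.54 to 251 ± 90.6 CPM (1.04). Of 27 p53 targets 13 rose and 10 fell (camera adjusted p = 0.662), with falls of the antiproliferative gene BTG2 (-2.56) and the kinase PLK3 (-2.44). NF-kB targets and cytokines divided into 8 that rose, 9 that fell and 4 that did not pass (camera adjusted p = 0.662), with NFKB1 higher and IRF1, an interferon regulatory factor, lower (-2.03). The median (0.02) and mean (0.21) of this list were above 0, and the direction of its test was down. Among 45 cell cycle genes 24 fell, 4 rose and 17 did not pass (camera adjusted p = 0.143, and 0.0354 without differentiated replicate 2), with CCNE2 lower and thymidylate synthase, TYMS, higher (0.88).

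The strongest list in this comparison was that of the ribosomal proteins: all 70 rose, 48 of them by at least 2-fold, with a median of 1.07 (camera adjusted p = 3.44e-42; adjusted p = 0.242 with an estimated correlation). Their counts may be shared with processed pseudogenes. Matrix genes rose in 33 of 37 cases and fell in 2 (camera adjusted p = 1.38e-13; adjusted p = 0.386 with an estimated correlation). Beside them stood 10 of 11 fibroblast markers that rose (1.39e-05 and 0.242 in the same order) and the higher share of FN1 and COL1A1 counts given above. Genes for chaperones and the unfolded protein response (21 of 25 rose and 3 fell, or 21 and 4 adjusted over the list alone; 6.49e-07 and 0.242) passed with the preset correlation only. The same held for NRF2 targets (15 of 21 rose and 2 fell; 3.10e-04 and 0.242) and ceramide synthesis genes (11 of 19 rose and 4 fell; 0.00819 and 0.399). The ceramide list did not pass with library totals only (0.0694). None of the 11 lists called for AICAR kept its call with an estimated correlation. With library totals only the median of the ribosomal proteins was 0.61, and that of the matrix genes 0.49 (0.95 with TMM factors). For unfolded protein response genes it was 0.41 (0.85 with TMM factors), and for nuclear respiratory chain genes 0.29 (0.74). Each of these lists kept its camera call with library totals only. Smooth muscle (5 of 9 rose and 3 fell; camera adjusted p = 0.63), endothelial (2 of 7 rose; 0.662), leukocyte (1 of 5 rose; 0.721) and neural markers (2 of 5 rose; 0.692) did not pass.

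The third comparison asked how differentiated cells respond to palmitate. Genes that sense and handle fatty acids were among the largest rises under the fixed rule, and 25 genes in all rose by at least 4-fold. PDK4, the kinase that restrains pyruvate dehydrogenase when fat is burned, rose from 0.39 ± 0.356 to 41.2 ± 5.32 CPM (n = 4 in each group). ANGPTL4, an inhibitor of lipoprotein lipase, rose from 8.48 ± 3.49 to 203 ± 7.54 CPM. CPT1A, which carries long-chain acyl groups into mitochondria, rose from 18.4 ± 2.93 to 87.1 ± 3.67 CPM, and PLIN2, the coat protein of lipid droplets, rose from 24.9 ± 1.70 to 98.0 ± 4.82 CPM. Log2 fold changes (± SE) were 6.73 ± 0.28 for PDK4, 4.58 ± 0.22 for ANGPTL4, 2.24 ± 0.12 for CPT1A and 1.98 ± 0.12 for PLIN2, with edgeR adjusted p-values of 3.01e-10, 9.41e-09, 3.01e-10 and 7.79e-10. Without differentiated replicate 2 the change of PDK4 was 7.54. PDK4 (ENSG00000004799.8) spans 95583499 to 95596491 on the minus strand of chromosome 7, and CPT1A (ENSG00000110090.13) spans 68754620 to 68844410 on the minus strand of chromosome 11.

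With palmitate 2370 genes were higher and 2790 lower (edgeR, adjusted p below 0.05), and 247 and 301 of them by at least 2-fold. With all libraries thinned to the same total, 153 of these 247 rises had a value, and 79.08% of the 153 kept the call. Of the 301 falls 228 had a value, and 86.4% of the 228 kept it. Rises made up 45.9% of the calls with TMM factors and 59.2% with library totals only, which moved the median change of all genes by 0.06 log2 units. The largest falls under the fixed rule were all of genes that act in mitosis or are used as proliferation markers: IQGAP3 (-2.06), PIMREG (-2.04), FAM83D (-1.96), MKI67 (-1.91) and the kinesin KIF18B (-1.89). ZBTB16 was among the 5 largest rises (1.70) at a level of 0.37 ± 0.0553 CPM, and it did not pass with limma on the deposited variance-stabilised values (adjusted p = 0.061).

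**Figure D3:**
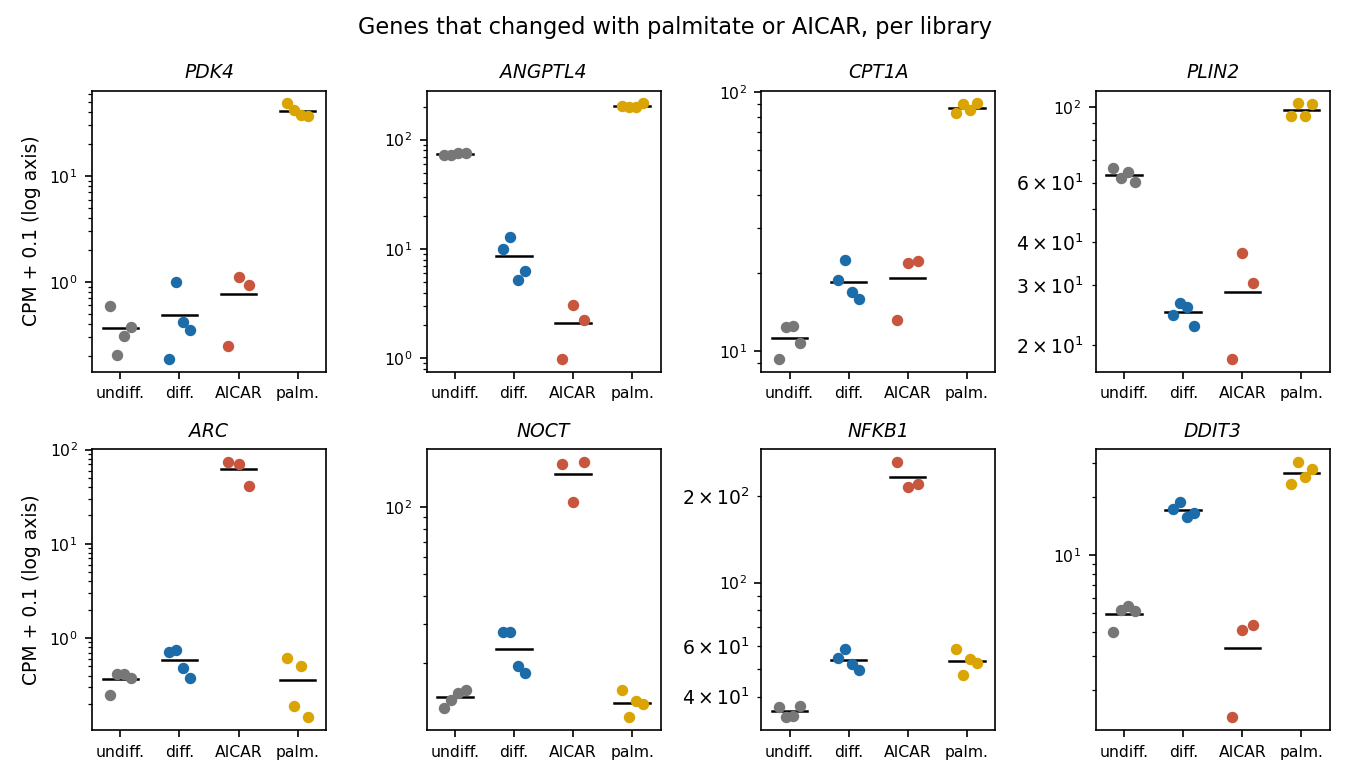
CPM plus 0.1 on a log axis for PDK4, ANGPTL4, CPT1A, PLIN2, ARC, NOCT, NFKB1 and DDIT3 in the 4 groups, with 1 point per library and a line at each group mean. PDK4 lies near 41.2 CPM with palmitate and 0.39 CPM in differentiated cells, and ARC near 61.5 CPM with AICAR and 0.482 CPM in differentiated cells.

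Among 19 lipid-responsive targets of PPAR receptors 11 rose, 1 fell and 7 did not pass (12 and 1 adjusted over the list alone), with a median of 0.52. The list passed in both forms of the test (camera adjusted p = 9.21e-17; adjusted p = 5.35e-05 with an estimated correlation). Fatty acid oxidation genes rose in 10 of 20 cases and fell in 1 (11 and 2 adjusted over the list alone; camera adjusted p = 1.29e-05; adjusted p = 0.122 with an estimated correlation), led by CPT1A and ACSL1 (0.82). Fatty acid synthesis and desaturation genes rose in 7 of 19 cases and fell in 1 (9 and 1 adjusted over the list alone; 1.22e-08 and 0.0271 in the same order). The stearoyl-CoA desaturase SCD rose from 1138 ± 84.0 to 3588 ± 299 CPM (1.66), and the delta-5 desaturase FADS1 rose by 1.18 log2 units. Sterol genes rose in 12 of 25 cases and none fell (13 adjusted over the list alone; 1.71e-04 and 0.122), including INSIG1, which holds back the sterol response (0.65). Ceramide synthesis genes divided (3 rose, 4 fell and 12 did not pass; camera adjusted p = 0.864), with the glucosylceramide synthase UGCG lower (-0.86) and the acid ceramidase ASAH1 higher (0.30).

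Glucose handling genes rose in part: 8 of 26 glycolysis genes rose and 2 fell (camera adjusted p = 0.00536; adjusted p = 0.515 with an estimated correlation), with rises of PFKFB4 (1.01) and TXNIP (0.79). SLC2A4 rose from 0.287 ± 0.159 to 0.83 ± 0.11 CPM (1.502), and PPARGC1A rose from 3.67 ± 0.946 to 7.12 ± 0.51 CPM (0.96). Insulin signalling genes did not pass as a list (6 rose, 4 fell and 13 did not pass, or 6 and 5 adjusted over the list alone; camera adjusted p = 0.864). IGFBP3, an insulin-like growth factor binding protein (-0.82), and RPTOR, a subunit of mTOR complex 1 (-0.37), fell. Nuclear respiratory chain genes stayed divided (7 rose, 9 fell and 42 did not pass; camera adjusted p = 0.886), from ATP5ME (0.43) to ATP5MC1 (-0.49). Hypoxia-inducible genes rose in 11 of 20 cases and fell in 2 (camera adjusted p = 2.42e-06; adjusted p = 0.0139 with an estimated correlation). Atrophy and autophagy genes rose in 16 of 28 cases with 1 fall (8.22e-06 and 0.0139 in the same order).

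Stress responses to palmitate were selective. DDIT3 rose from 17.1 ± 1.36 to 26.8 ± 3.12 CPM (0.65), while the chaperone HSPA5 measured 803 ± 31.6 CPM with palmitate and 849 ± 45.2 CPM without (edgeR adjusted p = 0.686). Integrated stress response targets divided into 11 that rose, 10 that fell and 12 that did not pass (11 and 11 adjusted over the list alone; camera adjusted p = 0.509). They ran from SESN2, a stress-induced inhibitor of mTOR complex 1 (1.01), to the proline synthesis enzyme PYCR1 (-0.80). The median of this list was -0.04 and its mean 0.12. Unfolded protein response genes did not pass (3 rose and 7 fell of 25; camera adjusted p = 0.533), with ERO1B higher (0.55) and SEC61B lower (-0.35). NRF2 targets rose in 9 of 21 cases and fell in 1 (camera adjusted p = 6.06e-04; adjusted p = 0.122 with an estimated correlation). AKR1C1, which has near-identical paralogs that may share its reads, rose by 1.26 and the haem oxygenase HMOX1 by 0.54. Inflammatory genes did not pass (4 rose, 3 fell and 14 did not pass; camera adjusted p = 0.874). IL6 measured 1.42 ± 0.281 CPM with palmitate and 1.64 ± 0.321 CPM without (edgeR adjusted p = 0.499), and IRF1 (-0.57) and the cytokine LIF (-0.74) fell.

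Contractile genes did not move as a list (9 rose, 10 fell and 27 did not pass of 46; camera adjusted p = 0.864), with a rise of KLHL41 (0.75) and a fall of MYBPH (-0.67). In contrast, 42 of 45 cell cycle genes fell and none rose, 29 of them by at least 2-fold, with a median of -1.23 (camera adjusted p = 1.32e-28; adjusted p = 0.122 with an estimated correlation). Ribosome biogenesis genes fell in 15 of 27 cases (19 adjusted over the list alone; 1.20e-04 and 0.122 in the same order). Regulators of myoblasts fell in 9 of 20 cases with 1 rise (9 and 3 adjusted over the list alone; 0.00168 and 0.0228). Smooth muscle markers fell in 7 of 9 cases and rose in 1 (8 and 1 adjusted over the list alone; 2.66e-06 and 0.0228). Smaller shifts that passed with the preset correlation alone were rises of interferon-stimulated genes (7 of 29; camera adjusted p = 0.00181; adjusted p = 0.722 with an estimated correlation) and of calcium handling genes (5 of 21; 0.0247 and 0.552 in the same order). Among p53 targets 8 of 27 rose and 3 fell (0.0261 and 0.483), and among immediate early genes 7 of 19 fell and 2 rose (9 and 2 adjusted over the list alone; 0.00536 and 0.483). The calcium handling call was lost without differentiated replicate 2 (adjusted p = 0.152) and without palmitate replicate 2 (0.0681), and the p53 call without differentiated replicate 3 (0.0661). Fibroblast (5 of 11 rose and 2 fell; camera adjusted p = 0.236), endothelial (1 of 7 rose and 1 fell; 0.541), leukocyte (2 of 5 rose; 0.416) and neural markers (1 of 5 rose and 1 fell; 0.801) did not pass.

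**Figure D4:**
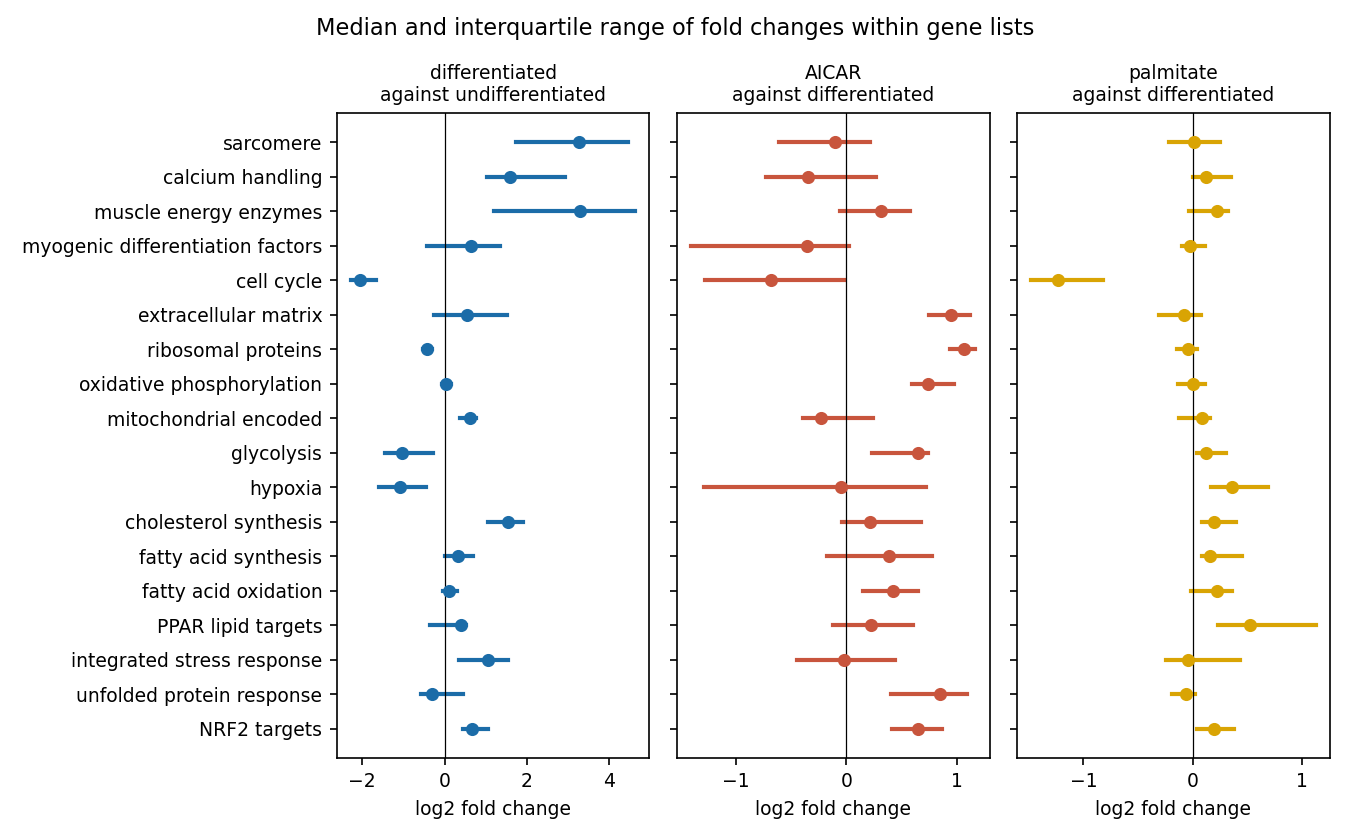
Median (point) and interquartile range (line) of the log2 fold changes of the members of 18 gene lists in differentiated against undifferentiated, AICAR against differentiated and palmitate against differentiated cells, with TMM factors. The sarcomere list lies at 3.27 with differentiation and the cell cycle list at -1.23 with palmitate, and these medians change sign with another setting: with AICAR, fatty acid oxidation, fatty acid synthesis, sterol synthesis, PPAR targets and muscle energy enzymes (library totals only) and hypoxia and the integrated stress response (DESeq2 size factors), and with library totals only also the nuclear respiratory chain with differentiation and the stress response, myogenic factors and ribosomal proteins with palmitate.

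The fourth comparison set the AICAR cells against the palmitate cells, which is the direct test of the difference between the responses because the shared control cancels. Lipid handling genes were among the largest differences: ANGPTL4 stood at 2.00 ± 1.05 CPM with AICAR (n = 3) and 203 ± 7.54 CPM with palmitate (n = 4), and PDK4 at 0.667 ± 0.46 and 41.2 ± 5.32 CPM. DDIT4, a stress-induced inhibitor of mTOR complex 1, and CHAC1, an enzyme that degrades glutathione, were also lower with AICAR, at 5.99 ± 1.02 against 156 ± 17.97 CPM and 1.58 ± 1.32 against 35.2 ± 5.85 CPM. ARC (61.5 ± 18.2 against 0.264 ± 0.231 CPM), NOCT (139.8 ± 29.9 against 13.3 ± 1.53 CPM) and MYC (135 ± 9.87 against 21.8 ± 1.46 CPM) were higher with AICAR. Log2 differences (AICAR minus palmitate) were -6.59 for ANGPTL4, -5.83 for PDK4, -4.69 for DDIT4, -4.36 for CHAC1, 7.74 for ARC, 3.39 for NOCT and 2.63 for MYC, with edgeR adjusted p-values between 1.96e-17 (MYC) and 3.56e-09 (DDIT4). Without AICAR replicate 3 the difference of CHAC1 was -5.35. MYC (ENSG00000136997.21) spans 127735434 to 127741434 on the plus strand of chromosome 8.

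Here 4860 genes were higher and 5698 lower with AICAR (edgeR, adjusted p below 0.05), and 1261 and 2842 of them by at least 2-fold. Rises made up 46.0% of the calls with TMM factors and 19.8% with library totals only, which moved the median by -0.51 log2 units and turned 437 calls to the opposite direction. The rest of the largest differences were those of MIR503HG (-5.37, and -6.54 without AICAR replicate 4), ESM1 (2.43) and CXCL8 (4.38, and 2.7 without AICAR replicate 4).

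PPARGC1A was lower with AICAR than with palmitate (-0.99; -1.56 without AICAR replicate 4 and -0.66 without AICAR replicate 1), and so was MYH3 (1929 ± 126 against 3616 ± 491 CPM, -0.91). Of 46 sarcomere genes 13 were higher and 19 lower with AICAR (camera adjusted p = 0.63), with the tropomyosin TPM1 higher (1.15) and XIRP1 lower (-1.68). Among 19 PPAR targets 5 were higher and 9 lower (camera adjusted p = 0.105, and 0.0373 with thinned libraries or 0.0071 with only these 2 groups in the fit), including CPT1A (-2.17) and the cholesterol exporter ABCA1 (-1.59). Cell cycle genes were higher in 20 of 45 cases and lower in 4 (19 and 4 adjusted over the list alone; camera adjusted p = 0.0553). TYMS (1.32) and the ribonucleotide reductase subunit RRM1 (0.87) were among them, and the median of the list was 0.47 with TMM factors and -0.03 with library totals only. The list was called higher than other genes with library totals only (adjusted p = 0.00604), with limma (0.0127), with only these 2 groups in the fit (0.0334) and without palmitate replicate 1 (0.0236). Sterol synthesis genes divided (13 higher and 9 lower; camera adjusted p = 0.916), with MSMO1 higher (1.499) and SQLE lower (-1.33). So did integrated stress response targets (14 higher and 12 lower; camera adjusted p = 0.87), whose median was 0.10 and mean -0.36, with PYCR1 higher (1.56) and SESN2 lower (-1.52). NF-kB targets (7 higher and 8 lower; camera adjusted p = 0.87) had a median of -0.20 and a mean of 0.06, with NFKB1 higher (2.14) and the receptor TLR4 lower (-2.21).

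With AICAR the median of the ribosomal protein genes was 1.12, and 0.61 with library totals only. All 70 of these genes were higher with AICAR (camera adjusted p = 5.96e-41, and adjusted p = 0.242 with an estimated correlation). The same was true of nuclear respiratory chain genes in 53 of 58 cases (5.26e-14 and 0.242 in the same order) and of matrix genes in 32 of 37 with 2 lower (33 and 2 adjusted over the list alone; 5.26e-14 and 0.242). The mRNAs encoded by mitochondrial DNA did not follow: 2 of 13 were higher and 5 lower (camera adjusted p = 0.87), the list was called lower with the length and GC trend removed (median -0.85, adjusted p = 8.8e-04), and their share of the counts was 1.90% against 2.57% (exact permutation p = 0.0286). Fibroblast markers were higher in 10 of 11 with 1 lower (4.2e-04 and 0.242) and unfolded protein response genes in 20 of 25 with 3 lower (3.82e-07 and 0.242). Regulators of mitochondrial biogenesis were lower in 13 of 19 cases and higher in 2 (camera adjusted p = 0.0386; adjusted p = 0.242 with an estimated correlation). Myogenic differentiation factors were lower in 12 of 20 cases and higher in 3 (0.0275 and 0.439 in the same order). The biogenesis call was lost with a minimum CPM of 1, with thinned libraries, with the length and GC trend removed and with only the AICAR and palmitate libraries in the fit (adjusted p from 0.0545 to 0.0806). Myoblast fusion genes (7 of 10 higher and 1 lower; 0.00785 and 0.242), purine genes (15 of 23 higher and 3 lower; 0.0386 and 0.242) and smooth muscle markers (5 of 9 higher and 3 lower, or 5 and 4 adjusted over the list alone; 0.0337 and 0.268) also passed with the preset correlation. Ceramide synthesis genes (12 of 19 higher and 4 lower; 0.0101 and 0.282) and NRF2 targets (11 of 21 higher and 4 lower; 0.0479 and 0.421) passed in the same way. With library totals only the purine, NRF2 and ceramide calls were lost (adjusted p = 0.181, 0.14 and 0.0568) and the medians of these lists fell below 0, and with limma the smooth muscle call (0.276) and that of the myogenic differentiation factors (0.102) were lost. The purine and NRF2 calls were also lost with the length and GC trend removed (0.0831 and 0.0761), with thinned libraries (0.0551 and 0.054) and with a minimum CPM of 1 (0.0547 and 0.0545). The NRF2 call was lost as well with limma (0.064), with only these 2 groups in the fit (0.0534) and without palmitate replicate 2 (0.0651) or 3 (0.0561), and the smooth muscle call with a minimum CPM of 1 (0.0545). No list kept its call with an estimated correlation in this comparison.

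Because both treatments were measured against the same 4 differentiated libraries, the overlap of their responses was set against unchanged groups simulated with those controls. AICAR and palmitate shared 838 genes that were higher with both and 1162 that were lower with both, where independent lists of these sizes give 716 and 1005. A further 894 genes were higher with AICAR and lower with palmitate, and 757 were the reverse, against 842 and 854 for independent lists. Across genes, which are not independent replicates, Pearson's r of the fold changes was 0.13 and the simulated unchanged groups gave 0.287 (0.261 to 0.344 over 20 draws). These values of r cannot be ranked against each other. Fold changes of unchanged groups hold only noise and the shared controls, so their spread is small and the controls weigh more in r. The covariance is not divided by that spread and can be compared. The covariance was 0.058 against a simulated 0.0162, a difference of 0.0418. With the controls divided 2 and 2, so that the responses shared no library, r was 0.0856 on average (0.0322 to 0.127 over 6 divisions) and the covariance 0.0402.

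Along the differentiation change, palmitate fold changes had r = 0.0935 across genes (0.12 with the differentiated libraries divided 2 and 2; -0.0643 in simulated unchanged groups). In all, 1085 genes were higher and 1271 lower with both differentiation and palmitate, against 782 and 885 for independent lists. Here too the simulated values of r, for palmitate and for AICAR, are not on the scale of the observed ones, and the covariances can be compared. The covariance with differentiation was 0.0479 for palmitate, against -0.0146 in the simulation. For AICAR r was -0.0497 (-0.0339 with the libraries divided; -0.028 in the simulation) and the covariance -0.0587, against -0.00999 in the simulation.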

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

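These tests were applied to the 115 genes of the fixed rule and focal sets and to 8 measures of the libraries, and none was chosen after a result was seen. A library was listed when Dixon's ratio set it apart from the other 3 of its group, and groups of 3 (AICAR) were not tested. Of 369 groups of values 27 had such a library (7.32%), where about 1 in 20 is reached by chance. Differentiated replicate 4 and undifferentiated replicate 1 held 5 each. No library was left out for this reason, and the results without each library are given with the other settings.

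In undifferentiated replicate 1, ribosomal protein genes held 3.63% of counts (others 3.26 to 3.31%), and the fatty acid gene ACSL1 stood at 279 CPM (others 242 to 245), AGRN at 162 (176 to 177), KCTD11 at 30.4 (32.3 to 32.5) and the ectonucleotidase NT5E at 676 (746 to 757). In undifferentiated replicate 2, COL4A2 stood at 205 CPM (223 to 224), POLG at 60.7 (62.3 to 62.4) and RRM1 at 112 (120.1 to 122). FAM83D stood at 26.5 CPM in undifferentiated replicate 3 (22.8 to 23.2). In undifferentiated replicate 4, CACNB1 stood at 25.7 CPM (21.7 to 22.3) and PFKFB3 at 65.9 (59.8 to 60.7).

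In differentiated replicate 1, MYC stood at 24.9 CPM (23.1 to 23.4). In differentiated replicate 2, the desaturase FADS1 stood at 210.4 CPM (207 in the others) and LRP4 at 40.8 (49.2 to 50.5). In differentiated replicate 3, ATP5ME stood at 21.1 CPM (17.03 to 17.7), ETFA at 81.2 (77.9 to 78.1), IRF1 at 49.5 (61.6 to 64.0) and KCTD11 at 40.6 (49.3 to 51.0). In differentiated replicate 4, ATP1B4 stood at 26.4 CPM (64.0 to 67.2), FBXO32 at 119 (129 to 129.8), PPARGC1A at 2.25 (4.02 to 4.23), SESN2 at 39.8 (36.6 to 36.7) and TXNIP at 115 (102 to 103).

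In palmitate replicate 1, ESM1 stood at 5.84 CPM (4.36 to 4.54). TXNIP stood at 145 CPM in palmitate replicate 2 (189.9 to 199). In palmitate replicate 4, the lipase inhibitor ANGPTL4 stood at 215 CPM (199 to 201) and PFKFB3 at 76.1 (60.9 to 62.5).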

How the results depend on the processing

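The thinning and the removal of the length and GC trend are tests added after the data were seen, and all other settings were set in advance. Library totals only moved all gene counts that involve AICAR: AICAR against differentiated gave 2263 genes higher and 8742 lower (167 and 4812 by at least 2-fold), and AICAR against palmitate 2228 and 9027 (215 and 5201). With limma on the deposited variance-stabilised values 1438 genes were at least 2-fold higher after differentiation, and 81 were higher and 133 lower by 2-fold with palmitate; a minimum of 1 CPM left 162 at least 2-fold higher with palmitate, and a threshold of 0.01 left 1502 higher and 1806 lower. With calls of at least 2-fold, AICAR and palmitate shared 46 rises and 104 falls, and r was 0.0856 with controls divided 2 and 2. Along differentiation r for AICAR was -0.0339 with libraries divided and -0.0674 over called genes, and for palmitate 0.12 with libraries divided and 0.129 over called genes with libraries divided. An estimated correlation ended 15 (differentiation), 11 (AICAR), 10 (palmitate) and 12 (AICAR against palmitate) list calls, and fry added 11, 19, 6 and 13 and ended 1 with palmitate (interferon-stimulated genes, 0.0529). Replicate numbers did not track each other between groups (r from -0.177 to 0.122); with the number as a replicate block the calls were 5087 higher and 4899 lower (differentiation), 4672 and 5567 (AICAR), 2220 and 2602 (palmitate) and 4751 and 5574 (AICAR against palmitate), and calcium handling genes gained a call in the last (adjusted p = 0.0458). Without each library in turn the calls higher and lower ranged from 4847 to 5132 and 4656 to 5049 (differentiation), 4584 to 4899 and 5069 to 5633 (AICAR), 1952 to 2646 and 2264 to 2944 (palmitate), and 4629 to 4809 and 5212 to 5576 (AICAR against palmitate). The counting tool, separate cultures and exposure times are not given in the sources used here, AICAR libraries differ from the rest in depth, and the gene annotation of the tables differs in part from the release that gave coordinates.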

Other observations

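The tests on glucocorticoid-responsive genes, zinc finger genes and abundance, the thinned libraries, the length and GC trend and the sarcomere test were chosen only after the result was seen. The bounds of the AU-rich element test and of the test on genes of undifferentiated cells were set before, and how the spread is weighed in these tests was chosen after.

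Genes that glucocorticoids induce in many cells were far lower after differentiation. The steroid receptor co-chaperone FKBP5 fell from 429 ± 30.7 to 33.9 ± 3.35 CPM (-3.66), and it, ZBTB16 (-7.20) and the metallothionein MT1L (-4.05) were seen to fall before the group was listed. Of 16 further genes known to rise with glucocorticoid, listed without these 3, 12 fell, 3 rose (SGK1, RASD1 and CDKN1C) and 1 did not pass (KLF15). The falls include the metallothioneins MT2A (-3.10), MT1E (-2.91) and MT1X (-1.84). These are paralogs of MT1L, so they are not separate from a fall already seen. The clock gene PER1 (-2.24), the transcription factors KLF9 (-2.34) and TSC22D3 (-1.33) and glutamine synthetase, GLUL (-1.99), fell too. The median was -1.70 (camera p = 1.15e-11, and 0.0012 with an estimated correlation). Less glucocorticoid in the medium of differentiated cells could give this (it requires a median of -0.5 or lower, and the value was -1.7022), and so could differentiation itself, and the media are not given in the sources used here. A culture of both stages in the same medium, with and without dexamethasone, would separate the hormone from differentiation itself.

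Zinc finger genes were lower in the AICAR libraries. Of 503 genes with ZNF symbols, a set chosen after their values were seen because they fell, 378 fell, 273 of them by at least 2-fold, 31 rose and 94 did not pass, with a median of -1.13 (-1.58 with library totals only and -1.01 with the length and GC trend removed). Against other genes of the same level in differentiated cells, in 20 bins, their median differed by -0.90 log2 units, and 75.2% of them fell against 41.1% of the others. These values describe the set and do not test it, since it was picked for its fall. With palmitate 43 of these genes fell and 66 rose, and with differentiation 103 fell and 137 rose. Many are members of clusters with similar sequences, so reads may be divided between them. Other genes also fell: by their level in differentiated cells, 14.6% of genes below 1 CPM, 42.2% at 1 to 10 CPM, 44.1% at 10 to 100 CPM and 22.3% above 100 CPM fell with AICAR, and 12.9%, 18.6%, 34.9% and 63.3% rose. The median above 100 CPM, 0.42, is about as large as the shift of -0.45 that library totals only bring, so the rise of abundant genes depends on the scaling. The most abundant genes include the ribosomal proteins and the matrix genes, whose medians were 0.61 and 0.49 with library totals only. Zinc finger mRNAs, in turn, are known for short half-lives in other cells. Block of transcription for some hours, or measurement of decay with labelled nucleosides, would tell slower synthesis from faster decay.

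For the fall of many less abundant mRNAs with AICAR, lower depth is unlikely as the cause, because 84.83% of the 2749 genes at least 2-fold lower kept that call when all libraries were thinned to the same total (94.37% of those with a value). A trend with length and GC content is also unlikely for the falls, with 82.06% of them kept (83.46% of those with a value). Of the genes at least 2-fold higher, only 63.53% of those with a value were kept, while their median change went from 1.1574 to 1.1414. Decay through AU-rich elements would need a difference of at least -0.2 between genes with and without the element matched for abundance, and the difference was 0.0309 (bootstrap interval -0.019 to 0.0751, over the 81.9% of tested genes that had a 3' UTR). The bound of 0 set in advance against this explanation lies within that interval and -0.2 lies outside it, and the use of the interval was chosen after the value was seen. Low totals coincide with the treatment in all 3 AICAR libraries, so library preparation stays untested; AICAR libraries prepared from equal RNA with spike-in RNA would settle it.

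The fall of cell cycle genes with palmitate was decided by no single library: its median lay between -1.38 and -1.0484 (without differentiated replicate 3) when each library was left out, with 41 or 42 of 45 genes lower. Fewer remaining undifferentiated cells stay open. The 32 genes of undifferentiated cells outside the list had a median of 0.1545 (8 lower, 11 higher and 3 at or below the -0.6 that this explanation requires). Those 3 were ID1, CCBE1 and the DNA replication gene MCM10, and MYF5 did not pass (-0.17, edgeR adjusted p = 0.133). The set also holds FKBP5, MT2A and MT1L, named above with the glucocorticoid-responsive genes. Regulators of myoblasts, in contrast, fell in 9 of 20 cases (camera adjusted p = 0.00168, and adjusted p = 0.0228 with an estimated correlation). The median of that list was -0.22, which is also above -0.6. It holds ID1 and MYF5 as well, so it is not separate from the 32 genes. The median of the 32 genes met the bound of -0.2 set in advance against this explanation, but by less than their SD, 1.02. That SD also exceeds the distance of the median to -0.6. Without ANGPTL4, which palmitate raises, the SD is 0.642 and the distance 0.74. The SD is the spread of single genes and not the error of their median, so it cannot decide the question. A shift of all genes along differentiation is unlikely, since sarcomere genes had a median of 0.0109 (SD 0.385) where 59.8% of the differentiation change, the share of the cell cycle genes, requires 1.96. A partial shift stays open, because palmitate and differentiation shared 1085 rises and 1271 falls against 782 and 885 for independent lists, with a covariance of 0.0479 against -0.0146 in the simulation, and labelled DNA synthesis with cell numbers would show whether cells divide less or dividing cells are lost.

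In the splits of the libraries into groups of the same sizes, only the real grouping, 1 of 35, reached its number of calls in each comparison. Differentiation gave 10189 calls and the highest other split 0, and palmitate gave 5160 and 1. A split that mixes libraries of both groups turns a real difference into spread within its groups. Its low number of calls is therefore no measure of the calls that groups without a difference would give. AICAR against differentiated gave 10422 and the highest other split 6497, and AICAR against palmitate 10558 and 6357. These high values belong to splits that set 3 differentiated (or 3 palmitate) libraries against the fourth joined with the AICAR libraries, which keep the AICAR libraries together and so keep most of the real difference.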
